A study of Homo sapiens with 2 samples.

How the data were processed

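Gene expression was measured on single-channel Illumina bead arrays in 2 samples of 1 group. Both are human cells of the embryonic stem cell line HUES8 that had been differentiated in suspension to stage 6 of a protocol that makes stem-cell-derived beta (SC-beta) cells, the insulin-secreting cells of the pancreatic islet. Per the labels, the cells were sorted for NKX6-1 and insulin protein before RNA was isolated by MARIS, a method for RNA from fixed, stained and sorted cells, and the RNA was amplified with the Illumina TotalPrep kit and labelled with biotin. The 2 samples are biological replicates per the series design text, and their replicate numbers come from the sample titles. The design text says that they were normalized together with published arrays of adult islet insulin-positive cells, undifferentiated HUES8 cells and insulin-positive cells from earlier protocols. Those arrays were not analysed here, so no comparison between groups was made.

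The deposited values are intensities on a linear scale, 1 per probe and array, for 47323 probes. GenomeStudio, Illumina's array software, is named in the submitters' processing notes, without a version in the sources used here. The values show 2 further steps that the labels do not describe. They reach below 0, to -22.6, which is what background subtraction leaves, and 28.0% of probes on replicate 1 and 28.1% on replicate 2 were at or below 0. The sorted values of the 2 arrays differed by at most 0.155, which is what quantile normalization leaves. Quantile normalization gives both arrays the same distribution, so a change shared by all genes cannot be seen, and a gene at the same rank on both arrays gets the same value. No detection p-value per probe was used here.

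Probes were named from GEO's platform annotation. Of the probes, 30113 had 1 gene, 8 had several and were not named, and 17202 were not listed and are unnamed here. Symbols were updated through the Entrez identifier in a RefSeq gene table for 30074 probes, and 39 kept the annotation's symbol. This gave 20046 named genes. No genome build is given in the sources used here, so no coordinates are printed.

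Background was set per array at the 95th percentile of 457 probes for olfactory receptor genes, which lay at 18.01 on replicate 1 and 15.9 on replicate 2. Receptor symbols with trailing letters, as pseudogenes have, were included. A probe was above background if it passed this floor on both arrays, and a gene if any of its probes did. Of 384 olfactory receptor genes, 8 were above background by this rule. Log2 values were taken after values under the floor had been set to it. A gene is represented by its brightest probe by mean log2 value, taken from the probes above background where there were any, and other probes of the same gene are described for some genes only. Fold values are given only where a probe was above background on both arrays. Where it was so on 1 array only, the fold is a lower bound against the floor of the other array, or against the probe's own value there if that was higher. A probe's brightness depends on the probe as well as on the RNA, so levels of different genes are not compared as amounts of RNA, and the order of probes by brightness serves to choose genes to name, to match random lists and to fit a trend. The brightness percentile of a list sets such levels side by side, and is for that reason given only as a number of lists, in the closing section.

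Before the data were examined, 24 gene lists were fixed for cell types, pathways and stress responses, together with the background rule, the alternatives and the rule for the genes to name. That rule took every measured member of the lists of beta-cell granule genes, islet transcription factors and other islet hormone genes, the first 4 measured members in written order of each other list with every detected member where fewer than 5 were detected, the 10 genes with the largest difference between the replicates in each direction, and the 20 named genes with the brightest probes that do not encode ribosomal proteins. Not every gene that it allows is named. Genes named outside it are said to have been chosen after their values were seen. Of 359 listed genes, 333 had a named probe. The others were not analysed here.

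With 1 group of 2 arrays no test between samples is possible and no p-value is given. For each list, the number of genes above background and the median brightness percentile of its genes among all named genes were set against 10000 random lists of as many named genes. The median log2 difference between the replicates, over the genes above background, was set against 10000 random lists matched on brightness in 20 bins. A list was described as outside the random lists if it lay above their 97.5th or below their 2.5th percentile. These percentiles describe the 2 arrays and are not p-values, since genes are not replicates. By chance about 1.2 of 24 lists would lie outside if the genes of a list were unrelated. Lists with fewer than 5 genes above background were left out of the last comparison. Tested on simulated differences for 9393 genes, with 10 genes in a list, the matched comparison placed 4 of 100 lists without a shift outside the random lists, 43 of 100 lists shifted by 0.5 on the log2 scale, and 94 of 100 shifted by 1. The simulated differences were independent and normally distributed, with fewer random lists in each simulation, so these rates may not hold for the real differences. The number of arrays limits the precision of every value. Means are given with the SD of 2 replicates, over intensities.

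Alternatives were other floors (the 90th and 99th percentile of the olfactory receptor probes, and the 95th percentile of 125 probes for keratin-associated proteins and taste receptors), each array alone, the median in place of the brightest probe, quantile normalization of the 2 arrays, median centring, no filter on background, and an offset of 50 before the log2 step. Removal of a running median over 501 genes in order of brightness, and a count over genes whose 2 or more probes all differed, were added after seeing the data. A second list of immediate-early genes, used in the closing observations only, was also drawn up after the data had been seen. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.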

Results

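Genome-wide expression was measured on 2 arrays, 1 for each biological replicate of stage 6 SC-beta cells sorted for NKX6-1 and insulin protein. The study set such cells beside adult human islet cells, undifferentiated stem cells and insulin-positive cells from earlier protocols. Those arrays were not analysed here, and 2 questions remained: which genes of the beta cell and of other cells were detected in the sorted cells, and how far the replicates agreed. Values are normalized intensities. Of 47323 probes, 16661 were above background on replicate 1, 17537 on replicate 2, and 14205 (30.0%) on both. By gene, 9393 of 20046 named genes (46.9%) were above background on both arrays.

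The hormone and secretory granule genes of the beta cell were detected almost without exception. Of 18 measured, 17 were above background on both arrays, more than in 99.995% of random lists. *INS*, which encodes insulin and whose protein was a sorting marker, had an intensity of 16501 on both arrays. *CHGA*, the granule protein chromogranin A, had 16785 ± 152 (SD, n = 2), *SCG5* 8592 ± 2491, *SCG3* 3480 ± 1470, *SCGN*, which encodes the calcium sensor secretagogin, 5511 ± 32.9, and *SLC30A8*, the granule zinc transporter, 2584 ± 243. *CPE*, a prohormone-processing carboxypeptidase, had 1745 ± 860, *ERO1B*, an oxidoreductase of the endoplasmic reticulum, 345 ± 13.2, *PTPRN2* 259 ± 35.9 and *VGF* 185 ± 37.6. *G6PC2*, the islet glucose-6-phosphatase subunit, had 1322 ± 925 at 1 of its 3 probes, and its other probes were not above background on both arrays. *GNAS* likewise had 12638 ± 1562 at 1 of 3 probes. *RBP4* was above background on replicate 2 only, with 7.32 and 50.6 on replicates 1 and 2.

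**Figure D1:**
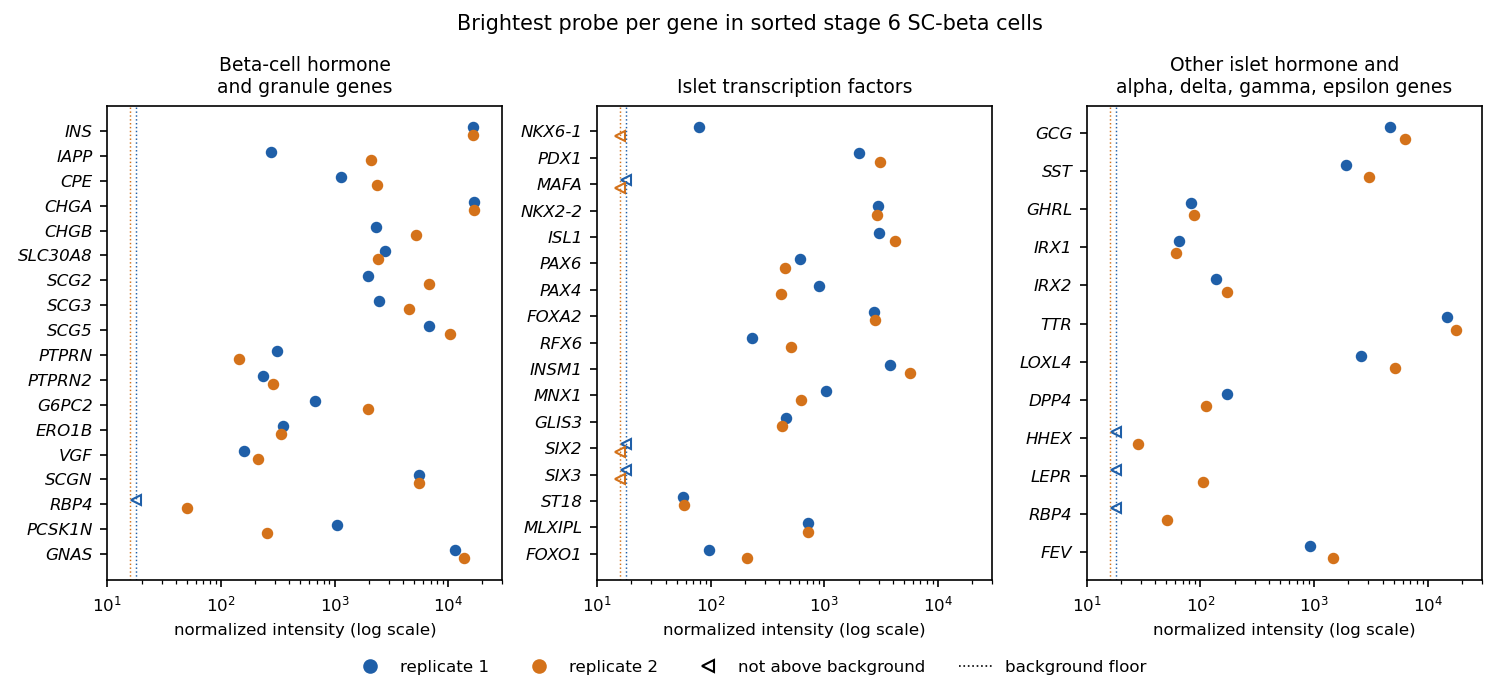
Normalized intensity of the brightest probe of each gene (log axis, arbitrary units) in replicate 1 (blue) and replicate 2 (orange) for the 3 fully named gene lists; dotted lines are the background floors of 18.01 and 15.9, and open triangles at the floor are values not above background. *INS* and *CHGA* lie at about the same value on both arrays, *IAPP* is 7.71-fold higher in replicate 2, and *MAFA*, *SIX2* and *SIX3* are not above background on either.

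Most islet transcription factors were detected, with *MAFA* and 3 others as exceptions. Of 17 measured, 13 were above background on both arrays, more than in 99.2% of random lists, but the list lay inside them on replicate 2 alone (96.4th percentile) and by the median probe of a gene (96.6th). *PDX1*, a regulator of pancreas development and of insulin transcription, had 2558 ± 737 at 1 of its 2 probes. *NKX2-2* had 2947 ± 36.9, *ISL1* 3573 ± 802, *INSM1* 4725 ± 1309, *FOXA2* 2750 ± 38.6 at 1 of 3 probes, *MLXIPL* 719 ± 0.839, *MNX1* 824 ± 283, *PAX4* 655 ± 339, *PAX6* 528 ± 113, *GLIS3* 444 ± 25.3 at 1 of 5 probes and *RFX6* 370 ± 198. *FOXO1* had 152 ± 79.2 and *ST18* 57.9 ± 0.753. *MAFA*, a transcription factor of mature beta cells, had 3.46 and 1.34 on replicates 1 and 2, and *SIX2* and *SIX3* were also not above background on either array. *NKX6-1*, whose protein was the other sorting marker, had a single probe, with 78.9 on replicate 1 and -4.24, not above background, on replicate 2.

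The genes for glucose sensing and insulin exocytosis were also detected more often than random lists, with 15 of 19 measured above background on both arrays (99.8th percentile, but 97.1st and inside the random lists by the median probe). *ABCC8* and *KCNJ11* encode the subunits of the ATP-sensitive potassium channel, and had 5813 ± 433 and 129 ± 22.7. The glucose transporter *SLC2A1* had 296 ± 148, whereas the other transporter *SLC2A2* had -2.24 and -10.7. The members not above background on both arrays, named after their values were seen, were *SLC2A2*, *RAB3A*, *GLP1R* and *CACNA1A*. Of the markers of beta-cell maturity, 9 of 14 were above background, within the range of random lists (89.3rd percentile). *UCN3*, which encodes the peptide urocortin 3, had -5.28 and 5.13, and it was not above background on either array, as was the case for *MAFA* and *SIX3*. *IAPP*, the hormone co-secreted with insulin, had 273 and 2107.

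Hormones of the other islet cells were detected in these insulin-sorted cells. *GCG*, the alpha-cell hormone glucagon, had 5476 ± 1231 (SD, n = 2), *SST*, the delta-cell hormone somatostatin, 2476 ± 781, and *GHRL*, ghrelin, 85.9 ± 3.70. In all, 9 of 12 measured genes of the list were above background on both arrays (97.2nd percentile, inside the random lists). The list lay above the random lists on replicate 2 alone, with 12 of 12 (99.975th percentile), at the 99th percentile floor (99.025th) and by the median probe (99.6th). They included *TTR* (16286 ± 2117), *LOXL4* (3860 ± 1814), *DPP4* (141 ± 42.5), *IRX2* (154 ± 22.8), *IRX1* (62.6 ± 2.89) and *FEV* (1184 ± 386). *HHEX*, a delta-cell transcription factor, *LEPR* and *RBP4* were above background on replicate 2 alone.

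Genes of enterochromaffin cells, the serotonin-producing endocrine cells of the gut, were above background in 9 of 12 cases (97.2nd percentile, inside the random lists, and 99.025th and above them at the 99th percentile floor). *TPH1*, the first enzyme of serotonin synthesis, had 71.7 and 275, the monoamine transporter *SLC18A1* 469 ± 122, and the transcription factor *LMX1A* 1088 ± 291 at 1 of 2 probes. *FEV* belongs to this list too. Among the 17 progenitor genes, 11 were above background (92.4th percentile). *NEUROG3*, the endocrine progenitor factor, had 13.9 and 13.3 and was not above background, nor was *PTF1A*. *SOX9* had 41.3 ± 14.2 and *HES1*, a Notch target, 22.9 and 170.

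Among genes of cell types outside the endocrine lineage, 2 lists were detected less often than random lists. Exocrine acinar genes (3 of 15, 1.84th percentile) and endothelial genes (1 of 10, 0.93rd percentile) lay below the random lists. The acinar list lay inside the random lists on replicate 1 alone, with 7 of 15 (35.2nd percentile), at the 90th percentile floor (3.32nd) and at the floor from keratin-associated proteins and taste receptors (5.95th), and the endothelial list by the median probe (4.05th). The detected acinar genes were *AMY2A* (191 ± 55.0), *AMY2B* (109 ± 15.7) and *CTRB2* (24.0 ± 10.02), each of which has a near-identical paralog that these probes may not separate, while *CPA1*, *CTRB1* and *PRSS1* were not above background on both arrays. The endothelial gene was *CLDN5*, with 99.5 and 23.1, and *PECAM1*, *CDH5*, *VWF* and *KDR* were not above background on either array. Pluripotency genes (5 of 17, 7.89th percentile) and blood and immune genes (3 of 10, 15.5th percentile) were within the range of random lists. *NANOG* and *LIN28A* were not above background on either array. *POU5F1* reached 18.4 on replicate 1 only and *SOX2* 74.9 on replicate 2 only. The 5 pluripotency genes above background, named after their values were seen, were *LIN28B* (415 ± 29.5), *DNMT3B*, *ZFP42*, *SALL4* and *LEFTY1*. Of the immune list, *CD68*, which encodes a lysosomal protein, had 721 ± 341, *AIF1* 250 ± 34.4 and *LYZ* 20.4 ± 5.86, and *PTPRC*, the pan-leukocyte marker CD45, was not above background. Among the definitive endoderm genes (5 of 12, 36.5th percentile), *SOX17*, *CER1* and *EOMES* were not above background on either array, and *CXCR4* had 68.9 ± 49.3 at 1 of 3 probes.

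**Figure D2:**
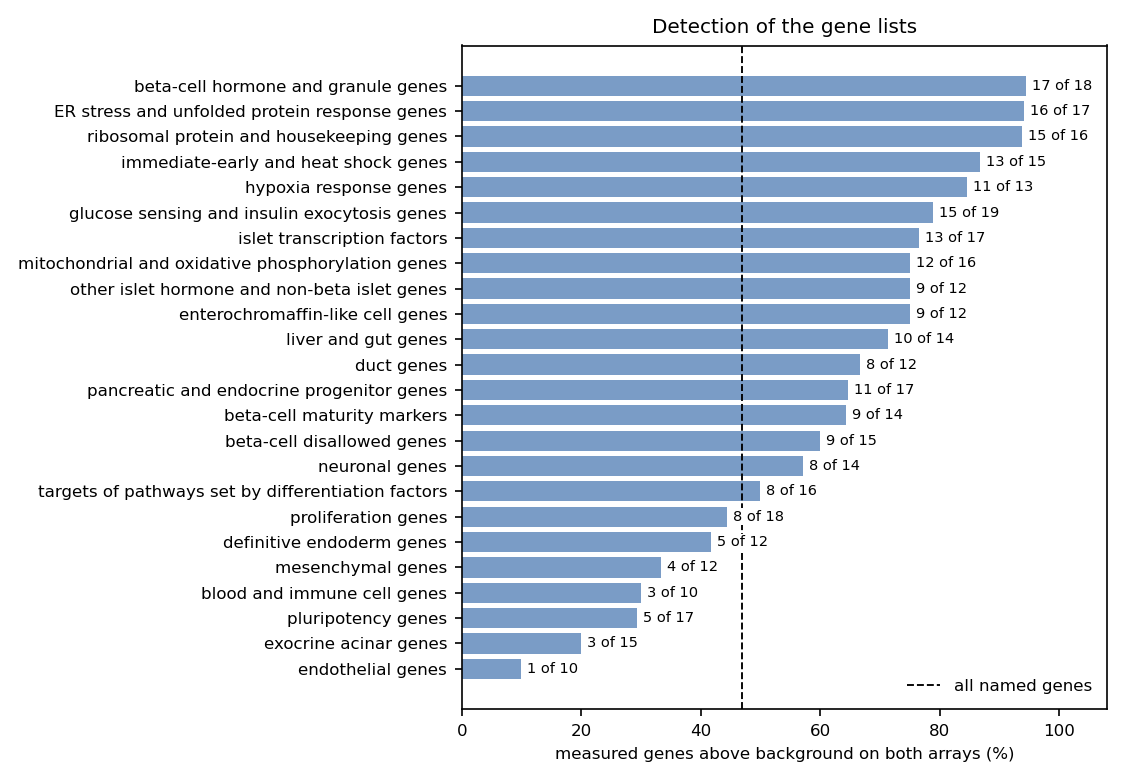
Share of measured genes above background on both arrays (x axis, percent) for each of the 24 gene lists (bars, with the counts); the dashed line is the share over all 20046 named genes, 46.9%. The beta-cell granule list is at 17 of 18 and the endothelial list at 1 of 10.

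Genes of liver and gut (10 of 14, 96.2nd percentile) and of ducts (8 of 12, 90.5th) were detected within the range of random lists. The duct list lay above them on replicate 2 alone, with 11 of 12 (99.6th percentile), and by the median probe (98.0th), and the liver and gut list at the 99th percentile floor (98.8th) and by the median probe (97.9th). *ALB*, albumin, had 332 ± 192, *AFP*, alpha-fetoprotein, 752 ± 351, the apolipoproteins *APOA1* 869 ± 469 and *APOA2* 1149 ± 665, and the epithelial keratin *KRT19* 974 ± 67.9. *CFTR*, a chloride channel of duct cells, had 29.3 and 216, and *SPP1* was above background on replicate 2 alone. Of the neuronal list 8 of 14 were detected (76.7th percentile), with *STMN2* at 3280 ± 1534, *TUBB3* at 1178 ± 732 and *DCX* at 747 ± 138, while *MAP2* had 7.39 and 19.8. Mesenchymal genes were above background on both arrays in 4 cases of 12 (18.2nd percentile), *VIM* with 166 ± 51.8, *TAGLN* with 159 ± 65.4, *COL1A2* with 43.2 ± 2.89 and *COL1A1* with 19.4 ± 0.929. On replicate 2 alone, 11 of the 12 were above background (99.6th percentile), and on replicate 1 alone 4 (10.9th). *COL3A1* had 12.3 and 76.6, and *PDGFRB* 14.2 and 17.8. Proliferation genes gave 8 of 18 on both arrays (41.0th percentile), 8 on replicate 1 and 14 on replicate 2. *MKI67* was not above background on either array, *TOP2A* had -2.05 and 85.4, *CDK1* 0.428 and 23.8, and *CCNB1* 21.6 and 75.7, 3.50-fold higher in replicate 2.

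Stress, metabolic and housekeeping genes were detected more often than random lists. The counts were 16 of 17 for the unfolded protein response (99.995th percentile), 13 of 15 for immediate-early and heat shock genes (99.9th), 11 of 13 for hypoxia response genes (99.5th), 12 of 16 for mitochondrial genes (98.7th, but 97.4th and inside the random lists at the 90th percentile floor) and 15 of 16 for ribosomal protein and housekeeping genes (99.995th). The chaperone *HSPA5* had 565 ± 13.8, *ATF4* 4525 ± 1174, *XBP1* 1696 ± 454 and *DDIT3* 269 ± 183. *VEGFA* had 677 ± 107.5 and *BNIP3* 2433 ± 764, and *PDK1* was not above background. *ATP5F1B*, a subunit of ATP synthase, had 7879 ± 1147. Of the genes that beta cells are known to keep low (9 of 15, 83.7th percentile), *LDHA* had 1008 ± 344 and *HK1* 98.6 ± 56.3, whereas *REST* was not above background on either array. Targets of the signalling pathways that differentiation factors set gave 8 of 16 (60.9th percentile), with *ID1* at 1878 ± 789, *ID2* at 1166 ± 818 and *ID3* at 1040 ± 130. Altogether 8 of 24 lists lay above the random lists in detection and 2 below. The random lists were drawn from all named genes, of which 46.9% were above background. Lists of widely expressed genes can exceed them in most cells. With no control group, the stress and hypoxia counts therefore do not show that such a response was active.

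The replicates were then compared with each other. Over the probes above background, log2 intensities correlated across probes with Pearson's r = 0.885 and Spearman's rho = 0.854, and the SD of the difference was 0.960. Probes are not independent replicates, so these values carry no p. Of 9393 genes, 2298 (24.5%) differed by 2-fold or more at their brightest probe, 1272 higher in replicate 2 and 1026 lower. The median gene was 0.21 higher in replicate 2 on the log2 scale. After median centring over probes, the split was 900 higher and 1239 lower. With an offset of 50 before the log2 step 1045 genes differed by as much, and among 1844 genes with 2 or more probes above background 388 did so at the brightest probe (237 higher and 151 lower) and 138 at every one of them. With 1 array per replicate, none of these differences has a replicate check, and in 31.5% of those 1844 genes the differences of the probes lay 2-fold or more apart. Several genes named here are among them. On the log2 scale the difference at the brightest probe and at another was 0.88 and -3.69 for *ID1*, 1.57 and -1.08 for *ID2*, -0.12 and -2.42 for *EEF1A1*, 0.65 and 2.83 for *VIM*, -0.72 and -2.11 for *MNX1*, -0.44 and -1.76 for *PAX6*, 1.24 and -0.16 for *HK1*, 0.54 and -0.76 for *ATF4*, 1.15 and -0.04 for *RFX6*, -0.08 and -1.17 for *ERO1B*, and 0.99 and -0.05 for *STMN2*.

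Among genes above background on both arrays, those with the largest positive differences included immediate-early genes, which respond to a stimulus within minutes. *FOS* was 20.3-fold higher in replicate 2 (111 and 2250), *NR4A2* 10.9-fold and *EGR1* 10.6-fold. The neuropeptide *NPY* was 9.96-fold higher, *TERF1*, which encodes a telomere-binding protein, 9.99-fold, *NKX3-2* 9.44-fold, the corepressors *TLE4* 9.43-fold and *TLE1* 8.04-fold, *CRYM* 8.56-fold (with 21.4 and -5.68 at its other probe) and *IAPP* 7.71-fold. The largest negative differences were at *ANPEP*, an aminopeptidase, 41.0-fold lower in replicate 2 (703 and 17.1), *RPS2*, a ribosomal protein gene, 31.4-fold, the translation elongation factor *EEF1G* 30.3-fold, *R3HDM4* 29.3-fold, *IRF2BPL* 27.6-fold, *CELF3* 25.8-fold, *SLC25A1* 23.2-fold, *PPP3R1* 22.1-fold, *APH1A* 21.4-fold and *WDR45B* 20.3-fold. Of these 20 genes only *NR4A2* and *APH1A* had more than 1 probe above background. Among the genes above background on both arrays, 60 were 8-fold or more lower in replicate 2 and 9 higher.

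Several gene lists differed together between the replicates. Of 20 lists with enough detected genes, 5 lay above and 1 below the central 95% of matched random lists. Chance would put about 1 outside if the genes of a list were unrelated. Genes of a list can vary together, and some are in more than 1 list, so the count does not measure an excess over chance. The maturity markers had a median log2 difference of 1.37, above all 10000 random lists. It covers the 9 of 14 measured genes above background, without *MAFA*, *UCN3* and *SIX3*. All 9 were higher in replicate 2, 7 by 2-fold or more. They included *IAPP* (2.95), *G6PC2* (1.57) and *CHGB* (1.18), while the granule list they share these with had a median of 0.28 (68.4th percentile), with *SCG2* 1.79 higher, *PCSK1N* at -2.03 and *PTPRN* at -1.13. Pathway targets had 1.08 (99.86th percentile), with *HES1* at 2.89 and with *ID1* and *ID2* at 0.88 and 1.57, although both of these were lower in replicate 2 at their other probe (-3.69 and -1.08). With the median of a gene's probes in place of the brightest their value was 0.29 (63.6th percentile), so this call depends on the probe chosen.

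The liver and gut genes had a median difference of 0.87 (99.83rd percentile), with 8 of 10 higher, *ALB* at 1.25 and *APOA2* at 1.25, but *APOA1* at -1.16. The immediate-early and heat shock genes also had 0.87 (99.8th percentile), with 9 of 13 higher. After removal of a brightness trend their median fell to 0.49 (98.6th percentile). *JUN* was 1.97 higher, and *FOSB*, not above background on replicate 1, was at least 27.5-fold higher in replicate 2, whereas *JUNB*, named after its values were seen, had 25.04 and -5.51 and was at least 1.58-fold lower. The hypoxia list had 0.65 (97.7th percentile), with *ADM* at 1.77, but lay inside the random lists at the stricter floor (94.8th percentile) and after removal of a brightness trend (97.1st). Quantile normalization of the 2 arrays left its median at 0.65, and against the random lists drawn then it lay at the 97.4th percentile, so this list is at the edge. Ribosomal protein and housekeeping genes had a median of -0.19 (2.15th percentile), with *RPS3* at -1.26, *RPL4* at -0.29, *RPL3* at -0.14 and *RPL5* at 0.28. After removal of the brightness trend this list lay at the 2.505th percentile, inside the random lists. The lists of islet transcription factors (0.03, 22.8th percentile), glucose sensing and exocytosis (0.17, 46.3rd) and other islet hormones (0.30, 65.2nd) lay within the random lists. Still inside them, glucose sensing and exocytosis turned to -0.15 with the median probe (12.9th percentile). Islet transcription factors turned to -0.20 after removal of the brightness trend (17.5th).

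**Figure D3:**
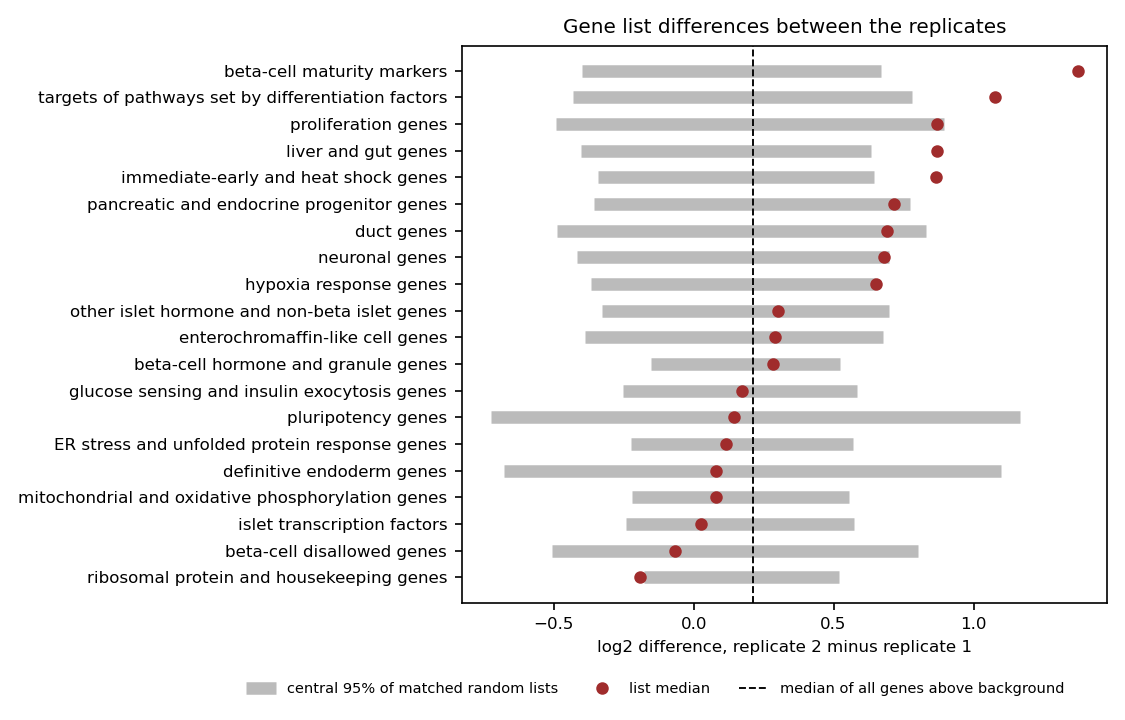
Median log2 difference between the replicates (x axis, replicate 2 minus replicate 1) for the 20 gene lists with 5 or more detected genes (red points), with the central 95% of 10000 brightness-matched random lists (grey bars) and the median of all 9393 detected genes, 0.21 (dashed line). The maturity markers lie farthest to the right, at 1.37, and the ribosomal protein and housekeeping genes farthest to the left, at -0.19.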

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

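Chosen or changed only after results were seen were the tests on other probes of the same gene, on the correlation of the probes of a gene, on the brightness trend at probes lower by 8-fold, on a second list of immediate-early genes, and on genes of other cell types. A signal appeared in data that no list used: 2738 probes with no gene name here were above background on both arrays, 15.9% of such probes against 38.1% of named ones.

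Among the probes above background on both arrays, 128 were at least 8-fold lower in replicate 2 and 9 at least 8-fold higher. The tables argue against a brightness trend left by the normalization, since the running median of the difference at the brightness of these 128 probes lay between 0.0897 and 0.29. To examine lower RNA of the whole gene, 6013 named probes bright enough on replicate 1 to show such a fall were taken, including those not above background on replicate 2. Of these, 199 fell this far. In the 79 of their genes with another of these probes, the other probes had a median of -1.004 (95% bootstrap interval -1.49 to -0.62), lower in 65 genes and higher in 14. A median of -1.5 or lower was required. The median lay above that bound, and the lower end of its interval (-1.49) did so only by a narrow margin. The fallen probes were picked for their fall, so other probes can be expected to fall less in any case, and the bound cannot decide. A bound of -1, tried after that value was seen, would also leave lower RNA open, so it stays a candidate explanation for part of the pattern. Over 1844 genes with several detected probes the intraclass correlation of the difference was 0.389 (0.352 to 0.424), so that on average part of a difference is the probe's own. An example is *ACTB*, named after its values were seen, where 1 probe had 1831 and 5.99 (at least 115-fold lower in replicate 2) while the others were 1.40-fold and 1.66-fold higher. The position of a probe on its transcript, through which RNA integrity acts, was not tested, nor was a biological explanation.

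Most immediate-early genes above background on both arrays were higher in replicate 2. A second list of such genes was written after the first list's values, and the differences of 2 of its members, *NR4A2* and *MAFF*, had been seen. Without those 2 its median difference was 1.61 over 15 detected genes, 13 of them higher. That was above all 10000 matched random lists, as a general activation of these genes would give. Both lists together, without those 2 genes, had a median of 1.17, and of 0.98 after removal of a brightness trend. Most of the difference thus stayed, which argues against such a trend as its source. The random lists were already matched on brightness, so their percentile was no separate test of it. The heat shock genes of the first list went both ways, with *HSPH1* at 1.13, *HSPB1* at -1.06 and *HSPA1B*, near-identical to *HSPA1A*, at -2.41, although the probe of *HSPA1A* itself was at 0.87, all named after their values were seen. Whether an activation arose in culture, in dissociation or in the sort may not be read from these arrays, and no biological explanation was tested.

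Genes of some other cell types were also higher in replicate 2. This was first seen in the duct, liver and gut, mesenchymal and progenitor lists, and a percentile for lists picked in this way means little. All 10 lists of cell types outside the islet and enterochromaffin lists were therefore put together, also after their values were seen, and had a median of 0.64 over 56 genes, 38 of them higher and 3 also held by another list. This was above all 10000 matched random lists. The 4 lists first seen to be higher hold 32 of the 56 genes, 24 of those 32 higher, so this percentile means little too. By 2-fold or more, 12 of the 56 genes were higher and 8 lower, against 10 and 3 of the 32. After removal of the brightness trend the median was 0.32, with 34 genes higher (99.8th percentile). The random lists were matched on brightness and the picked lists are in the pool, so this percentile was no separate test of such a trend. More cells of other types in replicate 2 is a candidate explanation that cannot be told apart from a wider difference between the samples, because the beta-cell maturity markers were higher too (1.37), a condition added after their values were seen. The lists are also not exclusive to a cell type: *FEV* is in the other islet list too, and *FOXA2* in that of islet transcription factors. Whether the insulin-sorted cells themselves expressed the pooled genes cannot be told from these arrays. *ALB* (1.25), *AFP* (0.99), *APOA2* (1.25) and *CFTR* (2.88) were among the higher genes and *APOA1* (-1.16), *TAGLN* (-0.87) and *KRT19* (-0.14) among the 18 lower ones, and genes above background on 1 array only do not enter, although of the mesenchymal list 11 of 12 genes were above it on replicate 2 and 4 on replicate 1. Over all named genes the shares were 54.8% on replicate 2 and 51.8% on replicate 1. The floor was lower on replicate 2 (15.9 against 18.01), so a dim gene could pass there alone. Of the mesenchymal list this holds for *PDGFRB* (17.8 on replicate 2) and *DCN* (17.96). It does not hold for *COL3A1* (12.3 and 76.6), *ACTA2* (10.4 and 69.0) and *FN1* (6.30 and 23.3), which passed the higher floor on replicate 2. Except for *COL3A1* and *PDGFRB*, these were named after their values were seen. Types did not all follow: of the neuronal list 6 of 8 genes were higher (median 0.68), but *CD68* (-1.002), *LYZ* (-0.59), *AIF1* (-0.28), *CLDN5* (-2.11) and *CTRB2* (-0.88) were lower, and acinar genes were above background in 7 of 15 cases on replicate 1 and 3 on replicate 2. The cells were sorted for NKX6-1 and insulin protein, but the purity of the sort was not measured here, and the *NKX6-1* probe had 78.9 on replicate 1 and -4.24, not above background, on replicate 2.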

How the results depend on the processing

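The count over genes whose 2 or more probes all differed and the removal of a brightness trend were chosen after seeing the data. No paired analysis was possible because there is 1 group. The number of probes above background lay between 11795 and 16003 under the other floors, and between 16661 and 17537 on 1 array alone. Between 7 and 11 of 24 lists were above the random lists in detection, against 8, with 8 to 10 on 1 array alone, and 10 to 11 in brightness, against 12, with 11 on either array alone. Beside 1 array alone, the lists whose detection changed side under another floor or the median probe were those of islet transcription factors, glucose sensing, mitochondria, acinar, endothelial, other islet, enterochromaffin, duct, and liver and gut genes. The count for a single list moved by more than 1.5 times in 8 of 144 repeats: with 1 array alone for mesenchymal (11), proliferation (14), endothelial (2) and acinar (7) genes, with the median probe for acinar (0), endoderm (2) and mesenchymal (2) genes, and at the 99th percentile floor for endothelial genes (0). The correlation of the replicates was 0.933 over all probes, where values at the floor are equal, and 0.905 with an offset of 50. Genes that differed by 2-fold or more numbered 1045 with that offset, which shrinks the differences of dim probes, and 138 where every one of 2 or more probes had to differ, a smaller set of 1844 genes of which 388 differed at the brightest probe. The other settings gave 1640 to 3145, against 2298. Between 5 and 7 lists lay outside the random lists in their difference, against 6. The progenitor list, inside at first, came to lie outside in 3 repeats, and the neuronal and proliferation lists after trend removal. The maturity, liver and gut, and immediate-early lists stayed above the random lists in each of the 4 repeats. Of these, quantile normalization could change little, because the 2 arrays already had nearly the same distribution. The pathway targets did not with the median probe, the hypoxia list was inside in 2 repeats and, with its median unchanged at 0.65, by a narrow margin after quantile normalization (97.4th percentile), and the ribosomal protein and housekeeping list was inside by a narrow margin after trend removal (2.505th percentile). No list outside the random lists changed sign. Of 78 repeats of a list median difference 7 moved by more than the spread of random lists, 6 lower and 1 higher. The 78 include 20 from quantile normalization, none of which moved. Of 92 repeats of a list brightness 49 moved by more than the spread of the replicates, 21 higher and 28 lower. The single probes of *NKX6-1*, *MAFA*, *UCN3* and *IAPP* set the limit for those genes: a probe near background may miss its RNA, and 31.5% of genes with several detected probes had probes whose differences lay 2-fold or more apart.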

Other observations

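Among the 20 named genes with the brightest probes that do not encode ribosomal proteins were *CHGA*, *INS*, *TTR*, *EEF1A1* (with a log2 difference of -2.42 between the replicates at another probe) and *CRYBA2*, a crystallin gene with 13988 ± 1665 (SD, n = 2) at its brighter probe and 957 and 19.5 at the other. Several others were bright at 1 probe and at background elsewhere. *CCR6*, a chemokine receptor of leukocytes, had 14032 ± 1603 at 1 probe and at most 8.14 (mean of the 2 arrays) at its 2 other probes, and *LAIR1*, another leukocyte receptor, had 14608 ± 257 at 1 probe and 2.48 at the other. *ORC6*, a subunit of the origin recognition complex, had 17390 ± 1589 at 1 probe and -7.21 at the other. Of the 14 such genes with more than 1 probe, 8 had no other probe above background: *ORC6*, *FAM177A1*, *ITIH5*, *RRP7BP*, *LAIR1*, *FARSB*, *CCR6* and *SLC7A5P2*. Among all 3780 genes with several probes and any above background, 51.2% had no other probe above it. That share covers genes of any brightness, so it does not show that such a gap is usual for bright probes. *PDCD7* (16339), *TUBA3FP* (14471), *CLUAP1* (13242) and *ROCK2* (13237) had another probe above background, but with a mean of at most 229, 91.3, 124 and 142. Which transcripts these probes bind was not checked, so a single bright probe does not establish expression of the named gene.

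*KCNH6*, a potassium channel gene of the exocytosis list, had 2 of its 3 probes above background, with 11217 ± 944 at 1 probe, 123 and 33.9 on replicates 1 and 2 at another, and 1.53 and -4.11 at the last. *L1TD1*, a pluripotency-associated gene, had 15.1 and 443, at least 24.6-fold higher in replicate 2, and of the same list *SOX2* (-7.54 and 74.9), *SALL4* (4.68-fold) and *LEFTY1* (1.95-fold) were higher there too, while *DNMT3B* was 2.47-fold lower, *LIN28B* differed by 1.11-fold, and *POU5F1*, *NANOG* and *LIN28A* were not above background on replicate 2. The median difference of the 5 genes of this list above background on both arrays was 0.15 (34.2nd percentile of matched random lists). Of these 5 genes 3 were higher in replicate 2, with *ZFP42* among the lower ones. *VAMP2* and *STX1A*, genes of the vesicle fusion machinery with 1 probe each, were 16.1-fold and 5.88-fold lower in replicate 2, while *SNAP25* was 2.71-fold higher at its brighter probe. Of the 15 detected genes of the glucose sensing and exocytosis list, 4 were higher by 2-fold or more and 2 lower. The median of that list was 0.17 (46.3rd percentile). These genes of the second paragraph were named after their values were seen.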
